A study of Bos taurus with 8 samples.

How the data were processed

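Transcripts were measured on 8 two-colour bovine oligonucleotide arrays, each comparing a treated pool of 5 in vitro blastocysts with an untreated pool from the same fertilization run. Per the labels, the media of treated groups held T3 and T4 at 50 ng/ml, and the RNA of each pool was amplified before Cy3 and Cy5 labelling. The numbers 2 to 5 in the labels were read as 4 runs, each hybridized on 2 arrays with the dyes exchanged. The treated pool was in Cy5 on slide 137 and in Cy3 on slide 138.

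The deposited scanner files hold the foreground and local background of each spot as intensity, on a linear scale and without normalization, and these were the values used. The deposited matrix holds a log2 ratio per probe and array, and the authors' combined table holds 1 log2 ratio per probe over all arrays. The submitters' processing notes name R 2.12.1 and limma 3. No per-sample measurement column was left unused, a count of 0. The matrix was used as an alternative and the combined table as a comparison.

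Intensities were corrected with limma's normexp method (offset 50) for the local background and normalized by loess within each array with control spots at weight 0, in R 4.3.3 with limma 3.58.1. Log2 ratios were turned to treated over control, and the 2 arrays of a run were averaged, since they hold the same pools, which leaves n = 4. A probe counted as detected in a pool when its foreground was above the mean plus 2 SD of 153 negative control spots on both arrays. It was tested when detected in at least 3 of 4 runs in at least 1 condition, which kept 23958 of 43794 probes. A 1-sample linear model with moderated variances (limma, two-sided) was fitted to the run means, and p-values were adjusted by the Benjamini-Hochberg method over tested probes. The number of arrays limits the precision. Figures were drawn with matplotlib in Python.

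Each probe had 1 symbol or none. Of all probes, 20068 had a current symbol, 1644 had an older symbol that was updated through synonyms, 78 kept the platform's symbol and 22004 had none. Symbols and membership of chromosome X came from the ARS-UCD2.0 annotation. For each of 10168 tested genes the probe of highest mean intensity was used. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 when at least 5 genes were tested, which left 22 lists including chromosome X. Camera with an estimated correlation and fry were alternatives.

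The rule for naming genes was also fixed before the data were examined. Genes past an adjusted p under 0.05 with the same sign in all runs and on both slides came first. As fewer than 10 of either sign passed, the 12 highest and 12 lowest means were named among genes with an unadjusted p under 0.05, the same sign on all 8 arrays and at least 1.5-fold. Every detected member of the hormone handling list could be named, 2 to 4 members with the smallest p in every other list, and XIST and detected Y-linked genes as a check of sex. Genes named outside the rule are said to be so.

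Pairing by run was checked in separate channel values. The deviation of a treated pool from the mean of treated pools correlated with that of the control pool of its own run at r = 0.0503 in run 2, 0.444 in run 3, 0.352 in run 4 and 0.392 in run 5. The highest r with another run's control pool was 0.0788, 0.192, 0.139 and -0.218 in the same order. Both pools of a run were read from the same spots, which can raise r within a run. The check therefore cannot tell this from a biological pairing.

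The procedure was tested on simulated data with each probe's moderated spread and with independent probes, which real lists are not. In these data 13 of 23758 unchanged probes were called. A list of 73 genes shifted by 0.2 was recovered and 0 of 21 other lists were called. Alternatives changed the background correction, normalization, filter, treatment of the arrays of a run, moderation and weights, left out each run, or took the matrix values. On the run 4 array with the treated pool in Cy5, 1 spot lay far below its local background in Cy3 (a difference of -34478). This left the normexp fit in Cy3 with a background of -209 there, against 28.0 to 188 on the other arrays. In Cy5 the fitted background of the same array was -120, against 12.4 to 52.8 on the other arrays. The fit was kept as planned and a repaired version was added as an alternative.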

Results

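The comparison set pools of 5 bovine blastocysts produced in vitro with the thyroid hormones T3 and T4 in the medium against pools of 5 untreated blastocysts from the same fertilization run. No gene passed the adjustment for multiple tests in limma over 4 runs. By the brightest probe of each gene, the lowest mean in the treated pools was that of SIRT2, a deacetylase. It was at a log2 ratio of -1.11 and below its control in all 4 runs, but a dimmer probe of SIRT2 was at 0.18. Among genes with 1 sign on all 8 arrays, an unadjusted p under 0.05 and at least 1.5-fold, AZIN1, H2AZ1 and WNK1 were highest. The polyamine regulator AZIN1, the histone gene H2AZ1 and the kinase gene WNK1 had means of 0.90, 0.90 and 0.85. Each had its largest ratio in run 5, and other probes of AZIN1 were at 0.10 and -0.18. Subunits of the oxidative phosphorylation complexes were higher as a list in limma's camera test at a preset correlation, at a median log2 ratio of 0.20 and above 0 in 2 of 4 runs. That call was lost with an estimated correlation (adjusted p = 0.968) and in fry (adjusted p = 0.971).

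Of 23958 probes tested, 0 passed an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.997. At an unadjusted p under 0.05, 902 probes differed, 482 of them higher and 420 lower in the treated pools, where chance alone gives 1198. Of these 902, 204 also differed by at least 1.5-fold, 110 higher and 94 lower, against 60 higher of 194 without run 5. With median centring the split at an unadjusted p under 0.05 was uneven, at 690 higher of 844. That setting put the median of all tested probes at 0.05. The sign of the log2 ratio was the same in all 4 runs for 2638 probes, where chance gives 2995. On simulated data with each probe's moderated spread, 39 of 50 probes changed 2-fold and 49 of 50 changed 3-fold were called. At 1.5-fold it was 5 of 50. Measured spreads vary more than moderated ones, and probes changed 1.5-, 2-, 3- and 4-fold were simulated together, which eases the adjustment. These counts may therefore overstate what the real data could show. With 4 runs, an exact sign-flip test of a single gene cannot give a two-sided p under 0.125.

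Among the genes with the same sign on all 8 arrays, an unadjusted p under 0.05 and at least 1.5-fold, 39 were higher and 37 lower in the treated pools, and all 76 failed the adjustment. SIRT2 lay between -0.85 in run 2 and -1.41 in run 4, a 2.15-fold lower mean signal with an SD of 0.23 across runs, and its adjusted p in limma was 0.997. A dimmer probe of SIRT2 went the other way, at 0.18. RBM19, which acts in ribosome assembly, had the smallest spread of the 24 genes named, with a mean of -0.75 and an SD of 0.13. The dipeptidase DPEP1 was at -0.87, the mitochondrial calcium exchanger SLC8B1 at -0.85 and the translation initiation factor EIF4B at -0.78, each lower in all 4 runs. The interleukin antagonist IL1RN had a mean of -0.87 that ran from -0.10 in run 4 to -2.04 in run 5. The aldose reductase gene AKR1B1, at -0.79, ran the other way, from -1.68 in run 2 to -0.04 in run 5. LOC511302, TLK2, STAP2, TMED1 and LY6G6C completed the lower group, with means from -0.83 for LOC511302 to -0.74 for LY6G6C. Other probes of TLK2, TMED1, STAP2 and IL1RN lay nearer 0, at -0.02 for IL1RN and as near as -0.04 for TLK2 and -0.0092 for STAP2, and that of LY6G6C was at 0.03.

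On the higher side, run 5 gave the largest ratio for 11 of the 12 genes named. H2AZ1 was at 2.08 in run 5 and 0.24 in run 2, WNK1 at 1.92 in run 5 and 0.35 in run 3, and the splicing factor SNRNP27 at 1.88 in run 5 and 0.10 in run 2. AZIN1 reached 1.90 in run 5, and its other probes were at 0.10 and -0.18. The transketolase-like gene TKTL1 was the exception, at 1.51 in run 4 and 0.15 in run 5, and its other probe was higher as well, at 0.59. The lysozyme gene LYZ3, with a mean of 0.84, and CCDC66, with 0.81, were the steadiest, each with an SD of at most 0.42. SELENOH had a mean of 0.83. The mitochondrial genes NDUFB2, at 0.78, and COX6C, at 0.75, were highest in runs 2 and 5. DUT, which clears dUTP before replication, and the centromere gene CENPF had means of 0.72 and 0.71. The authors' combined log2 ratio for SIRT2 was -1.27 and for AZIN1 1.25, and across tested probes, which are not independent replicates, it correlated with the run mean at r = 0.931.

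**Figure D1:**
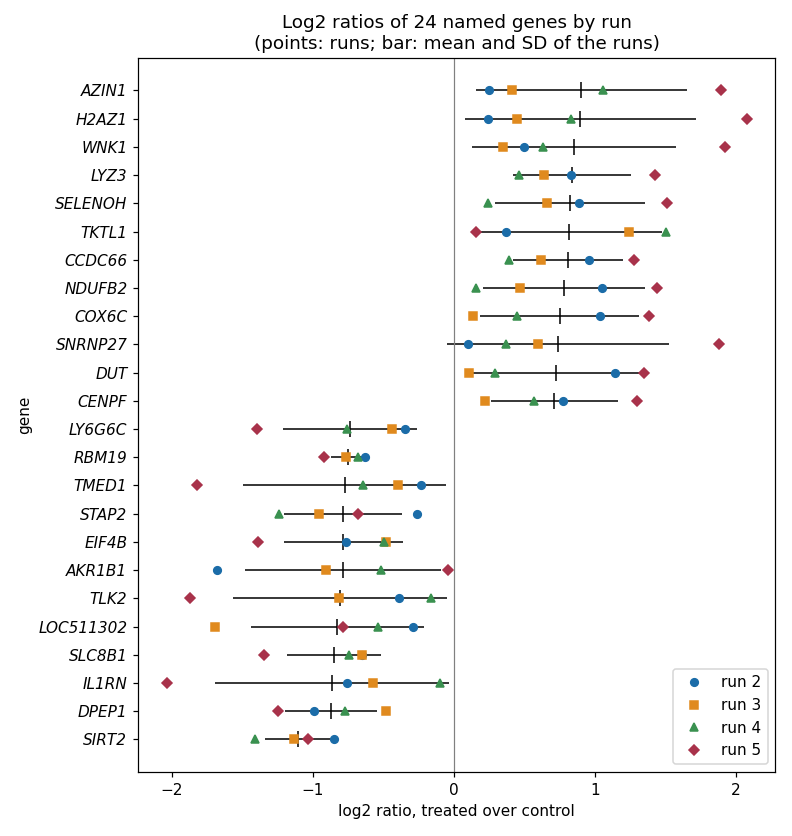
Each row is a gene, and the horizontal axis is the log2 ratio of treated over control signal. Points are the 4 runs, and the bar gives their mean and SD. The mean of SIRT2 is -1.11, and the points of RBM19 lie closest together, with an SD of 0.13.

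No shift was found in the list of genes that handle thyroid hormone. Of its 22 genes on the array, 13 were tested, and no deiodinase gene was among them. The receptor gene THRA was detected and had a mean log2 ratio of -0.09, with -0.45 in run 2 and 0.24 in run 5. THRB, the deiodinase genes DIO1, DIO2 and DIO3, and RXRA were not above background by the detection rule. Among cofactors, NCOA3 was at 0.37, NCOA1 at 0.22, THRAP3 at -0.19, NCOR1 at 0.10 and MED1 at -0.02. Other probes of NCOA1 and THRAP3 lay on both sides of 0, at 0.37 and -0.04 for NCOA1 and at -0.34 and 0.25 for THRAP3. The partner receptor RXRB was at -0.15. Of the transporters, SLC16A10 was at 0.14, SLC7A5 at -0.19 and SLC7A8 at -0.01, with SLC7A5 between 0.59 in run 2 and -1.10 in run 5. The hormone-binding genes CRYM and TTR were at -0.13 and 0.04, and the integrin ITGB3 at -0.08. Under 6 other scalings, the sign changed for SLC7A8 in 2 and for MED1 and ITGB3 in 1 each. The list of 13 genes had a median of -0.02, a mean of 0.00090 and an adjusted p of 0.921 in limma's camera test.

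Of 27 genes on the array that answer to thyroid hormone in other tissues, 14 were tested. Their median was -0.02, and the adjusted p was 0.908 in limma's camera test. The planned members KLF9, HR, THRSP and ME1 were not among those tested. The glucose transporter SLC2A1 was lowest in the mean, at -0.66, and was above 0 in run 2 alone, at 0.15, but another probe of SLC2A1 was at -0.10. The lipid synthesis gene ACACA was at -0.32 and the calcium pump gene ATP2A2 at -0.23, although other probes of ATP2A2 were at 0.05 and 0.32. No member of either hormone list passed, whether adjusted over all genes or adjusted over the list alone.

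Energy metabolism held the one list past the adjustment. The 73 oxidative phosphorylation genes had a median of 0.20, with 48 above 0 and 25 below, an adjusted p of 0.00040 in limma's camera test at a preset correlation, and an adjusted p = 0.968 with an estimated correlation. NDUFB1 at 0.69, NDUFA2 at 0.53, NDUFB2 and COX6C were each higher in all 4 runs, and at an unadjusted p under 0.05, 9 members were higher and 1 lower. That 1 was NDUFV3, at -0.35, named after its values were seen. The list's median was 0.37 in run 2 and 0.17 in run 5, and -0.05 in run 3 and -0.07 in run 4, so the direction was shown by 2 of 4 runs. Without run 2 the median was 0.07 and the adjusted p 0.812, without run 5 they were 0.11 and 0.00056, and without both runs the median was 0.00013 and the adjusted p 0.904. The 20 genes of glycolysis and of glucose and lactate transport had a median of -0.10 and an adjusted p of 0.116, and the median was 0.02 with median centring. At the preset correlation that list passed, downward, with scale normalization, with array weights, without run 5 and without runs 2 and 5. Over all 4 runs it had an adjusted p = 0.968 in camera with an estimated correlation and 0.971 in fry. Before adjustment, p was 0.011 in camera at the preset correlation, 0.068 with the estimated one and 0.085 in fry. The estimated correlation of that list was -0.037. PFKM at -0.39 and ALDOA at -0.59 were lower in all 4 runs, and TPI1, at -0.88, owed most of its mean to -2.32 in run 2. Fatty acid oxidation genes had a median of -0.06, with ACADL at 0.25 and PPARD at -0.19. The sterol genes had one of -0.07. HMGCS1 was at 0.30, with other probes of HMGCS1 at 0.20 and -0.19. MSMO1 was at 0.61, with 1.80 in run 5 and other probes of MSMO1 at 0.0081, 0.12 and 0.35. The fatty acid oxidation and sterol medians were above 0 with median centring, at 0.04 and 0.01. Like the 0.02 of glycolysis with that setting, they were below the median of all tested probes, 0.05. Neither the fatty acid oxidation list nor the sterol list passed.

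Markers of the blastocyst's lineages lay on both sides of 0 within each list. In the trophectoderm, the keratin genes KRT8, KRT18 and KRT19 had run means below 0 in all 4 runs, at -0.59, -0.27 and -0.65 over the runs, but their arrays disagreed. KRT8 was at 0.55, 0.59, 0.12 and -0.17 on slide 137 and between -1.15 and -1.83 on slide 138. TFAP2C was higher in all 4 runs, at 0.62, with other probes of TFAP2C at -0.19 and 0.34. The trophectoderm list had a median of -0.09 and an adjusted p of 0.908. Of the epiblast genes, LIN28B was lower in all 4 runs at -0.51. KLF4, NODAL and DPPA3 were higher in the mean at 0.43, 0.26 and 0.26, with a list median of 0.05. The arrays of NODAL disagreed, from -0.17 to -0.77 on slide 137 and from 0.17 to 1.37 on slide 138. Primitive endoderm genes had medians from -0.34 in run 2 to 0.34 in run 3, and 0.05 over the runs, with APOA1 at -0.49 and PDGFRA at 0.21. Junction and blastocoel genes had a median of -0.10 over the runs and -0.31 in run 2. In runs 3, 4 and 5 it was 0.01, 0.25 and 0.13. Among them CLDN6 was at -0.34, CGN at -0.22 and DSP at 0.24, with other probes of CGN at 0.19 and 0.0077. Cumulus and granulosa genes, a check on carried-over somatic cells, had a median of 0.02, with SERPINE2 at 0.47, CYP19A1 at -0.30 and HSD3B1 at -0.58. Maternal transcripts had a median of -0.01, with DDX4 at 0.32 and BMP15 at -0.14. No member of these lists passed when adjusted over the list alone.

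Cell cycle genes lay on both sides of 0, 15 above and 13 below. TOP2A at 0.58, CCNB1 at 0.55 and TYMS at 0.35 were higher in all 4 runs, with other probes of TYMS at 0.02 and -0.04, and the cyclin gene CCND2 was lower in the mean at -0.59. The median of the 28 cell cycle genes was 0.00190 and its adjusted p was 0.805. SUZ12, at 0.54, and HDAC2, at 0.24, were the chromatin genes with the smallest p, and both were higher in all 4 runs, with other probes of SUZ12 both at 0.11, beside a list median of -0.01. The apoptosis list had a median of 0.09, with BAK1 at -0.41 and lower in all 4 runs, and BCL2L1 at 0.28. STAT2 was the interferon-stimulated gene with the smallest p, at -0.71, with MX2 at 0.17 and a list median of -0.01. In antioxidant defence, PRDX3 and PRDX1 were at 0.57 and 0.56, with 1.46 and 1.71 in run 5, and the list's median of -0.06 stood beside 0.54 in run 5 alone. Stress genes included TRIB3 at -0.67, DDIT3 at -0.38 and the chaperone gene HSPA5 at 0.48, and the heat shock list had medians of -0.29 in run 2, 0.49 in run 5 and -0.06 over the runs. SNRPN was at 0.30 and GRB10 at -0.19 among imprinted and growth factor genes, whose median was -0.02. Ribosomal protein genes had a median of 0.02, with RPL11, RPS12 and RPL3 lower in all 4 runs, at -0.42, -0.71 and -0.72, and RPL36A higher in all 4, at 0.66.

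Of 22 lists, 1 passed in camera at the preset correlation, 0 with an estimated correlation and 0 in fry. Apart from oxidative phosphorylation and glycolysis, the other 20 lists had adjusted p-values from 0.805 to 0.972 in limma's camera test. Adjusted over the list alone, 0 members passed in any list, as when adjusted over all genes. Of the members given 1 sign in all 4 runs, KRT8, KRT18, KRT19, ALDOA, TYMS, HDAC2, RPL3 and RPL36A did not have it on all 8 arrays. Leaving out 1 run moved the mean by over 1.5 times or changed its sign for 9 of the 24 genes named for size and for 79 of all 120 genes open to naming, 48 of them without run 5. Of the 40 such genes with other tested probes, all of those probes lay nearer 0 than the brightest for 32 genes, and at least 1 had the opposite sign for 14. Mean and median differed in sign for 7 lists, which were those of hormone handling, primitive endoderm, cumulus cells, maternal transcripts, antioxidant defence, chromatin modifiers and imprinted genes. The test's direction differed from the median's sign for 4 of these, namely hormone handling, maternal transcripts, chromatin modifiers and imprinted genes. Under 6 other scalings, 8 lists kept the sign of their median, among them oxidative phosphorylation, trophectoderm, junctions and ribosomal proteins. The other 14 did not. Antioxidant defence, heat shock and chromosome X changed with median centring alone, to 0.07, 0.10 and 0.02, where the median of all tested probes was 0.05.

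**Figure D2:**
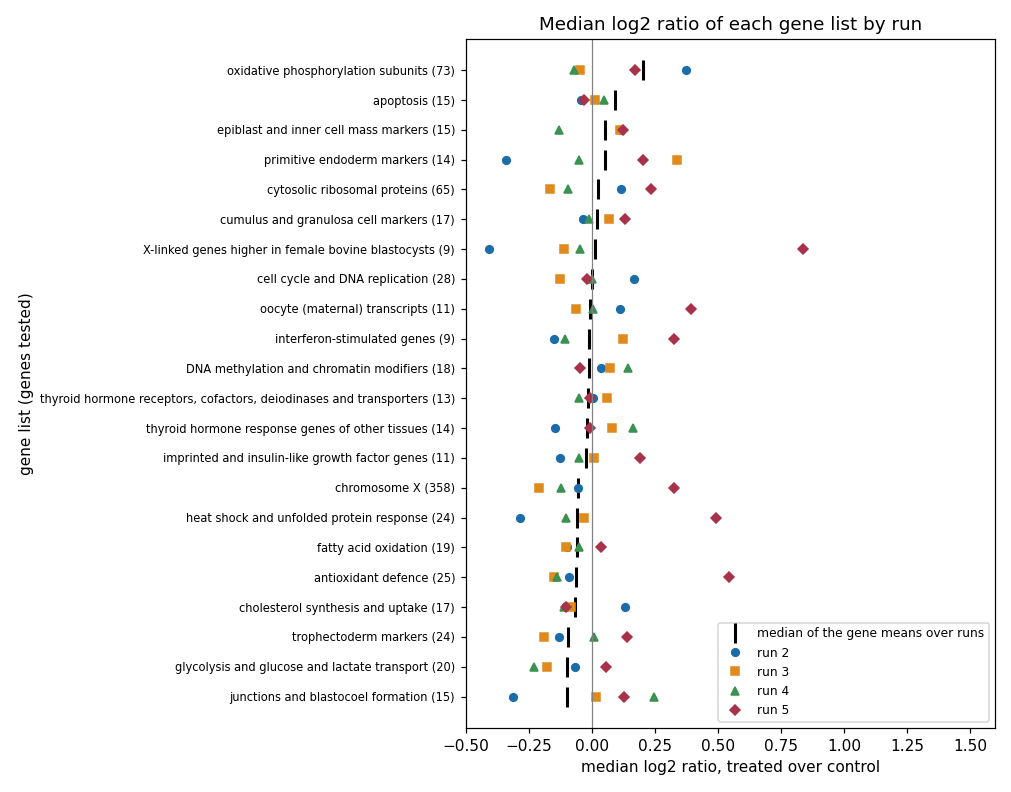
Each row is a gene list with its number of genes tested, and the horizontal axis is the median log2 ratio of treated over control. Points are runs and the black bar is the median of the gene means. Oxidative phosphorylation genes lie at 0.37 in run 2 and at -0.07 in run 4.

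XIST and chromosome X, a check of the sex make-up of the pools, differed between runs in sign and size. XIST was 2.37 higher on the log2 scale in the treated pool of run 5, at 2.49 and 2.25 in the 2 dye orientations. It was at -0.41 in run 2, -0.90 in run 3 and -0.04 in run 4. The 357 other X-linked genes had a median of 0.32 in run 5 against 0.04 for autosomal genes, and of -0.21 against -0.01 in run 3. In run 4 the X-linked median was -0.12 against -0.03, and in run 2 -0.05 against -0.01. The short list of X-linked genes chosen as higher in female embryos, which includes XIST, had a median of 0.84 in run 5 and 0.01 over the runs. HPRT1 was at 1.61 in run 5 and near 0 in the other runs, and BEX2 was at 1.83 in run 5 and -0.30 in run 3. Over all 4 runs, chromosome X had a median of -0.05, an adjusted p of 0.908 in limma's camera test and 0 members past the adjustment. Y-linked DDX3Y and EIF1AY had means of 0.17 and 0.16, and their signals had a median of 1.11 and 1.08 times the detection threshold. SRY, ZFY and TSPY were not above background by the rule.

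**Figure D3:**
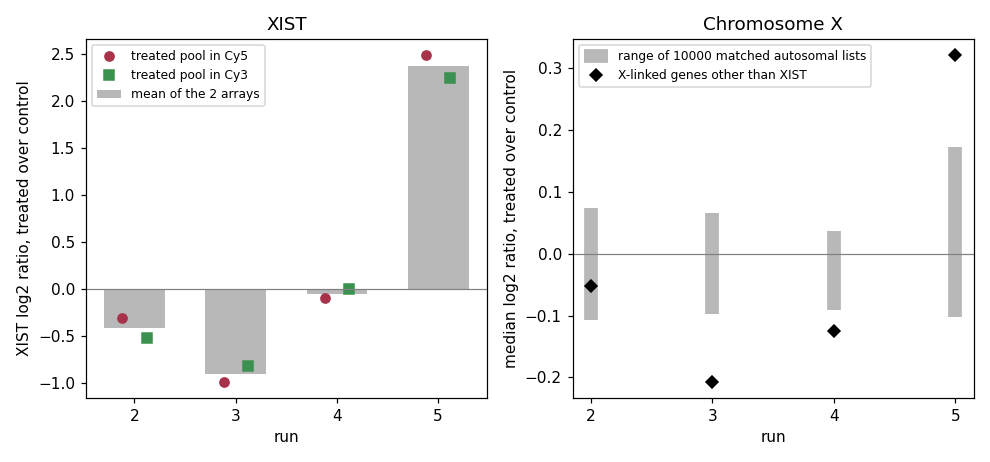
The left panel plots the log2 ratio of XIST for each run, as bars for the mean of 2 arrays and points for the arrays. The right panel plots the median log2 ratio of the other X-linked genes (diamonds) and the range of 10000 autosomal lists of matched intensity (grey). Run 5 lies above that range at 0.32, and runs 3 and 4 lie below it.

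Ratios repeated well within a run and poorly between runs. Across tested probes, which are not independent replicates, r between the dye orientations was 0.583 in run 2, 0.499 in run 3, 0.599 in run 4 and 0.736 in run 5. Between runs, r had a median of 0.0140 over 6 pairs, from -0.325 for runs 2 and 5 to 0.312 for runs 4 and 5. Genes at least 2-fold apart on both arrays numbered 670 higher and 280 lower in the treated pool of run 5, and 52 higher and 197 lower in run 2. In run 3 there were 23 higher and 52 lower, and in run 4 there were 26 higher and 37 lower. The array area was the same as the run and the slide the same as the dye orientation, so neither could be fitted apart.

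**Figure D4:**
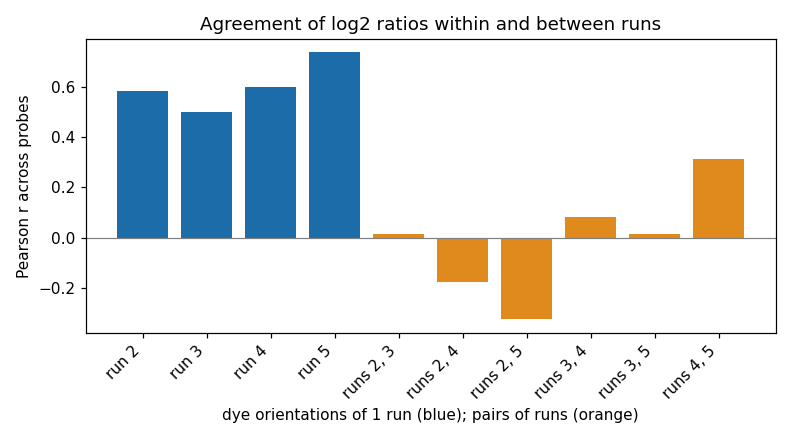
Bars give Pearson's r of log2 ratios across tested probes, for the dye orientations of each run in blue and for pairs of runs in orange. Within runs r is 0.499 or more, and between runs it is at most 0.312.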

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

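A check of the lowest and highest of the 4 runs against the other runs (Dixon's ratio, at its 95% limit) covered 156 measures of genes, lists and arrays. It picked out 13, and chance gives 7.8, at about 1 in 20. Run 5 stood apart for HPRT1 at 1.61, HSPA5 at 1.59, SERPINE2 at 1.47, SLC8B1 at -1.35 and Y-linked EIF1AY at -0.070, and for the median of antioxidant genes at 0.54. Run 2 stood apart for TPI1 at -2.32, RPL11 at -0.24 and the median of sterol genes at 0.13. Run 3 stood apart for CLDN6 at -0.98, and run 4 for the median of epiblast genes at -0.13. On slide 137, the array of run 5 had a median Cy3 signal of 399 and negative control spots at 298.5 in Cy3, both far above the other 3 arrays. The array of run 5 on slide 138 had a median Cy3 signal of 113, and the 2 arrays of that run agreed at r = 0.736 across probes.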

How the results depend on the processing

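Leaving out chromosome X, leaving out runs 2 and 5 together and repairing the background before normexp were chosen after seeing the data; the other alternatives were planned. The count of probes past the adjustment in limma was 0 in 21 of 22 alternatives and 1, SIRT2, with 8 arrays as independent (adjusted p 0.0188), which counts technical repeats as replicates. The 24 genes named for size kept their sign in all 527 values, and SIRT2 ranged from -0.91 to -1.39. These genes were chosen for 1 sign on all 8 arrays. Settings that only drop or reweight arrays could therefore not change it, and the kept signs are no independent check. The count at an unadjusted p under 0.05, 902, was 1651 with no filter, where more probes were tested, 2826 with 8 arrays as independent, 2220 on slide 137, 1561 on slide 138, 1640 with array weights, 1676 without runs 2 and 5, and 487 to 1900 leaving out 1 run, with 1900 without run 2 and 487 without run 4. Without the pairing by run (no replicate block) it was 476. With at least 1.5-fold, 204 became 344 with the run as a random block, 318 with 8 arrays as independent, 855 on slide 137, 586 on slide 138, 668 from the matrix values, 608 without runs 2 and 5, and 194 to 950 leaving out 1 run, with 950 without run 2 and 358 without run 3. Lists past the adjustment numbered 2 with scale normalization, 2 on slide 138, 2 with array weights, 2 without runs 2 and 5, 0 with an estimated correlation, 0 with fry, and 0 to 3 leaving out 1 run, with 0 without run 2 and 3 without run 5. Glycolysis passed, downward, with scale normalization, array weights, without run 5 and without runs 2 and 5, the last 3 with chromosome X downward too. Ribosomal proteins passed upward on slide 137, as the 1 list there, and downward on slide 138. As the treated pool was in Cy5 on slide 137 and in Cy3 on slide 138, both calls put the list higher in Cy5. That argues against a treatment difference, and over the run means the list had a median of 0.02 and an adjusted p of 0.921 in limma's camera test. For oxidative phosphorylation the adjusted p was 0.185 on slide 137, 0.0939 with array weights, 0.968 with an estimated correlation, 0.971 with fry, 0.812 without run 2 (7.86e-06 at the lowest leaving out 1 run), and 0.904 with the test's direction downward without runs 2 and 5. The median r between dye orientations was 0.475 with median centring. The matrix values put the median of all tested probes at 0.20, and 575 of their 668 probes were higher. Median centring put the median of all tested probes at 0.05, with 690 of 844 probes higher, and 254 of 279 at 1.5-fold. Without run 5, 60 of 194 were higher. Where not given, the cause was not tested. Signal over background limits dim genes, such as EIF1AY at 1.08 times the threshold.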

Other observations

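The intensity-matching tests, the test on autosomal genes and the splits of the lists were planned before their results were seen; the other tests here were chosen after. The genes in this paragraph were chosen after their values were seen. In run 2, BAG3 was at -2.96, HSPB8 at -2.45, HSPA1A at -2.44 and HSPH1 at -2.28, whereas in run 5 HSPA1A was at 1.23 and HSPH1 at 0.97. Of the 24 members of the heat shock list, 18 were below 0 in run 2, and HSPB1 was at 0.98 and HSP90AB1 at 0.46 there. The trophoblast genes TKDP1 and IFNT were at -2.51 and -2.54 in run 2, and at 2.61 and 1.04 in run 3. VIM went from -2.59 in run 2 to 1.95 in run 4, and COL9A2 from 1.76 in run 2 to -2.71 in run 5. CYP3A28 was high in run 4 alone, at 3.07. In run 5, CT47B1 reached 4.25, PRM1 2.89 and the epiblast gene CRIPTO 2.87, while each lay between -0.57 and 0.41 in the other runs. LOC786530 was at 2.85 in run 2 and 3.93 in run 5, and at -0.71 in run 4.

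XIST and X-linked genes were high in the treated pool of run 5. One dye or one faulty array is argued against by XIST at 2.25 or more in both orientations, and a shift with intensity by the X-linked median, above 100% of 10000 matched autosomal lists, and a hormone effect on XIST shared by the runs by the other runs, the highest at -0.044. A larger share of female embryos in that treated pool may explain it, since the other X-linked genes were 0.28 above autosomal genes, and in run 3, where XIST was at -0.90, by a difference of -0.20. Run 4 does not go with it, with XIST at -0.04 and a difference of -0.098. The X-linked median of run 4, -0.12, was below all 10000 matched lists, the lowest at -0.091. Leaving that range therefore does not by itself point to the sex of the embryos. Run 2 goes with a difference in the share of females less well, with XIST at -0.41 and a difference of -0.042. Y-linked genes lay too near the threshold to test it, and a hormone effect in run 5 alone was not tested.

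Oxidative phosphorylation genes were higher as a list, and brightness as the whole cause is argued against by their median, which was above 100% of 10000 matched lists. Genes that vary together from run to run may account for the call, because camera's p with the estimated correlation was 0.258 and the call ended without run 2. Better recovery of short abundant transcripts stays open, since ribosomal protein genes were below oxidative phosphorylation genes in run 2 and not in run 5, where the difference was -0.064 (95% bootstrap interval -0.35 to 0.50). A hormone effect on respiration stays open as well, at 2 of 4 runs in its direction.

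Oxidative phosphorylation and ribosomal protein genes had medians above 0 in both run 2 and run 5. Across tested probes, though, the log2 ratios of these runs were inversely, if weakly, related, at r = -0.325. Measurement noise is argued against by r = 0.583 or more between the dye orientations of both runs, and one slide or one dye by r between the runs of -0.140 within slide 137 and -0.209 within slide 138, where a shared dye bias would make r positive. Between runs 2 and 5, r was -0.343 over 9748 autosomal genes and -0.341 over all genes, so X-linked genes alone did not make it negative. X-linked genes are a small part of the genes tested, so leaving them out could hardly move r. The sex make-up of the pools cannot be weighed in this way and stays open. An effect of the array area, which is the same as the run, on the dye ratio would reverse in sign between the orientations. The r of 0.583 or more between them argues against it. Amplification of each pool and the embryos that made it up were not tested and stay open.

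The 4 runs can be turned in 8 ways, too few for a share under 0.05. The real arrangement gave 0 probes past the adjustment, as did 8 of 8 ways, with 0 at most in the others. It gave 902 probes at an unadjusted p under 0.05 (4 of 8 ways gave as many, the highest other 2698), 204 with at least 1.5-fold (5 of 8, the highest other 845) and 1 list (5 of 8, the highest other 3). The counts of 2698 and 845 came from turning runs 3, 4 and 5 against run 2, and turning runs 4 and 5 gave 2401. This points to a structure of the samples in which run 2 tends to oppose runs 4 and 5 across probes.

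The deposited matrix column for run 4 with the treated pool in Cy5 correlated with its scanner file's log2 ratio at r = 0.453 across tested probes, where the other 7 columns gave 0.805 to 0.923. It correlated with that array's log2 Cy5 intensity at 0.673, against at most 0.354 for the others.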
